A study of Solanum lycopersicum with 6 samples.

How the data were processed

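Small RNA from stem apices of tomato cultivar Ailsa Craig was sequenced in 3 healthy and 3 HSVd-infected samples. Per the labels' protocols, libraries were made with a TruSeq small RNA kit and read on an Illumina instrument, and ACGT101-miR version 4.2 removed adapter dimers, junk, low-complexity reads, common structural RNA families and repeats. The aligner, genome build, miRBase release and any read minimum are not given in the sources used here. Samples were assigned from their titles, and the table's CK columns were read as the healthy control and its H columns as HSVd-infected. This reading follows usage in the field and was not stated by a label, so it limits every direction.

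The raw columns of the deposited table hold expected counts per the file headers and values, since reads of a sequence listed at several loci were divided among its rows. Of all values, 22.1% were not whole. The norm columns deposited by the authors hold a signal, the raw value times 1 factor per library (0.699 to 1.65), and how the factor was set is not given in the sources used here. Of 1962 lines, 13 held no entry here and 1949 listed a microRNA. They held 1571 unique mature sequences, of which 376 stood on more than 1 row, all with identical counts on each row. Only 1 row of each sequence was used. A sequence on several rows thus kept only part of its divided reads. Its CPM, its share of counts and its part of a family sum are understated against those of sequences whose reads were not divided. The positions in the table span the listed hairpin in 1923 of 1923 rows that have one. No column of other samples was present. Total expected counts per library, with 1 row per sequence, ran from 1082522 to 2665440. Rounding to whole numbers before the count tests changed no library total by more than 0.00123%.

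Sequences were tested in edgeR 4.0.16 (R 4.3.3) with estimateDisp, glmQLFit and glmQLFTest, TMM normalization and filterByExpr at its default minimum count of 10 and total of 15. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The filter kept 672 sequences and 109 of 130 families. The family is the miR number in the name, whatever the species, letter, arm or variant. Standard errors are the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.271. CPM values use TMM-scaled library sizes. Lists (silencing, immune receptor, development, auxin, phase, nutrient, other Solanaceae families) and sets by length and of predicted candidates were tested with camera and fry in limma 3.58.1 on log2 CPM with a prior count of 2. The lists, the tests and the rule for named microRNAs were fixed before the data were examined. Shares of counts were compared by exact permutation tests in SciPy 1.17.1. Thinning drew binomial counts, summed over rows, 20 times.

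The rule named up to 8 called named sequences and 3 called predicted candidates in each direction, with non-overlapping groups and a mean of at least 5 CPM. It also named, for each list, the family with the smallest p and the one with the highest CPM, the 5 most abundant sequences, and the miR168, miR162, miR403, miR482, miR398 and miR159 families. If fewer than 5 sequences passed, the 10 with the smallest p were given and said not to pass. No list of cell type markers was used for these microRNAs, and animal-named sequences and those outside 20 to 24 nt served as signs of foreign or degraded RNA. Animal names were searched by the prefixes hsa, mmu, bta, ssc, dme and cel. The table holds only sequences kept by the authors' pipeline, so low values of these signs cannot show that the RNA was intact or free of foreign RNA.

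The fits were tested on simulated counts drawn from the real means and library sizes. Each simulation changed 200 sequences or 30 families, used the trended dispersion for all and drew them independently. With fewer real changes or more spread, the share recovered may be lower than given here. For sequences (626 tested), 13.3%, 42.4% and 93.7% of changes of 1.5, 2 and 4 fold were recovered, and 1.66% of calls were false. For families (105 tested) the shares were 16.3%, 56.8% and 98.0%, with 4.71% false. The immune receptor list, shifted by 1 log2 unit, was called by camera in 5 of 5 simulations, and unshifted in 0 of 5. Other sets were called 7 times in all with the shift and 0 times without it. Which sets these were was not kept. The sets by length share sequences with the shifted list, but the other lists share no tested family with it, so false calls of unshifted sets are not excluded. These simulations held no correlation within lists, which camera estimated in the data at 0.179 for silencing and 0.289 for nutrient. Alternatives were RLE and library-total scaling, no filter, a mean of at least 10 CPM, the replicate number as a block, each library left out, every row kept, named sequences only, DESeq2 1.42.0, limma on log2(norm value + pseudocount of 1, 0.1 or 10) for means of at least 1, and an estimated correlation. Counts summed over rows, sequences above 0 in all 6 libraries, a robust fit and the alternatives for the share outside 20 to 24 nt were added after seeing the data. The microRNAs named after their values were seen were carried through the alternatives after seeing the data too. The series title names another subject than the samples do, melatonin and the fungus Alternaria brassicae. Its design text describes another library kit, instrument and experiment than the samples' protocol, and that protocol counts more libraries than the 6 used here. The samples' labels and protocol were followed, and the other assays named in the series text are not analysed here.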

Results

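Mature microRNA sequences were counted in stem apices of tomato (Solanum lycopersicum, cultivar Ailsa Craig). There were 3 healthy libraries and 3 libraries from plants infected with HSVd, hop stunt viroid, a small circular RNA that replicates in plants without coding for a protein. The groups rest on reading the table's CK columns as the healthy control and its H columns as the infected plants. H could also abbreviate healthy, and every direction given here would then turn around. Total expected counts, with 1 row used for each of 1571 unique mature sequences, were 1818450, 1082522 and 1963440 in healthy replicates 1 to 3. In infected replicates 1 to 3 they were 1979860, 2284758 and 2665440. Over all rows the totals were 2014816, 1191760 and 2162877 in healthy and 2219857, 2519172 and 2912115 in infected replicates. Of the unique sequences, 792 carried a miRBase-derived name and 779 were predicted candidates. By length, 1080 sequences had 24 nt, 264 had 21 nt and 89 had 22 nt. Nothing in the labels says that the samples came from separate plants, so the p-values measure the spread between these samples, which may in part be technical.

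The infected libraries listed 1259 ± 82.5 sequences above 0 and the healthy ones 1052 ± 176 (mean ± SD, n = 3 each). Healthy replicate 2, the shallowest library, listed 851, and the others listed between 1127 and 1341. After all libraries were thinned to the smallest total with a minimum of 5 reads, the means were 830 in infected and 806 in healthy libraries. A listed 0 can hide a few reads, because among 3864 nonzero whole values of sequences on a single row only 15 lay under 5 and none was 1 or 2.

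**Figure D1:**
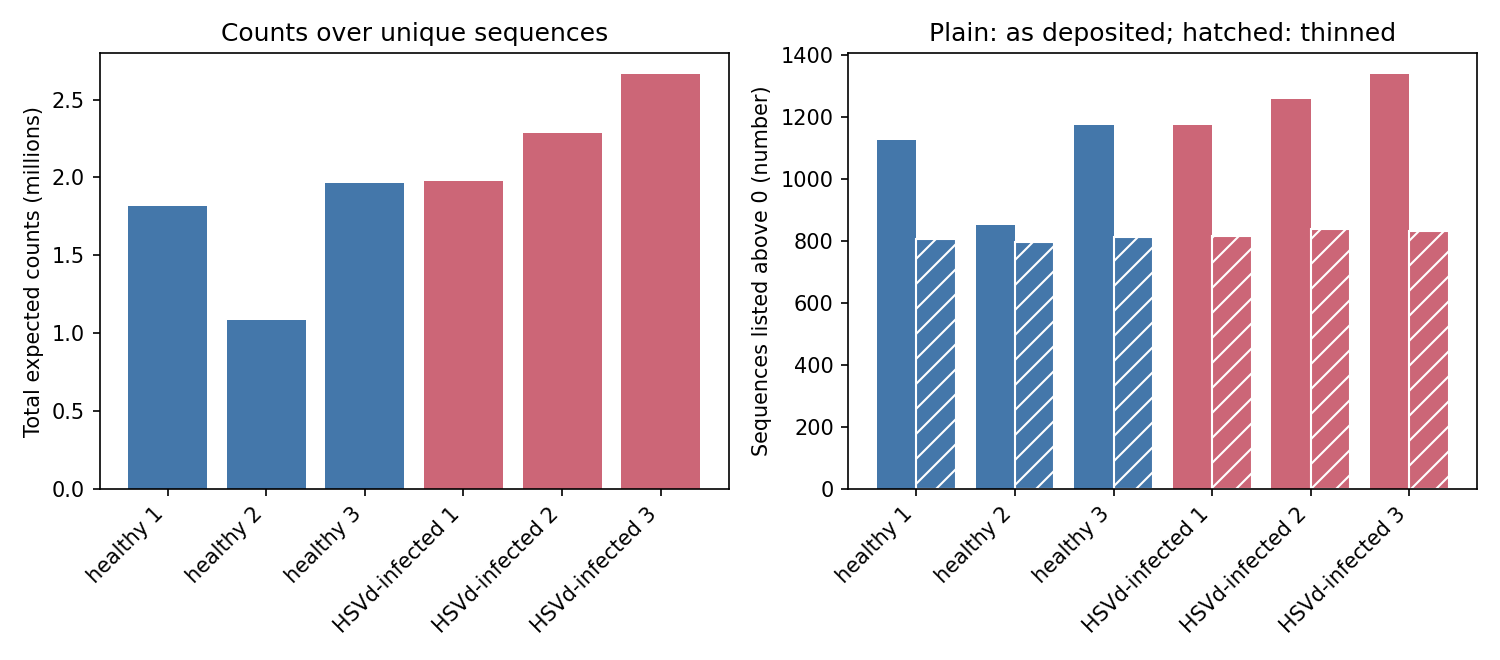
Total expected counts with 1 row used per sequence (left) and number of sequences listed above 0 (right) in each library, blue for healthy and red for HSVd-infected, with hatched bars for the number after thinning to the smallest library. The listed numbers run from 851 to 1341 as deposited, and the group means after thinning are 806 and 830.

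The first comparison asked how the size and class of the microRNAs differed between infected and healthy apices. Sequences of 21 nt, with 1 row used for each, held 52.3 ± 1.95% of counts in healthy and 50.4 ± 2.55% in infected libraries. Sequences of 22 nt held 42.2 ± 1.82% and 44.1 ± 2.62%, and those of 24 nt 3.44 ± 0.0956% and 3.52 ± 0.156% (SD, n = 3 each). Predicted candidates held 1.27 ± 0.0188% in healthy and 1.19 ± 0.0227% in infected libraries, with no overlap between the groups. The most abundant sequence of each library held 20.6 ± 0.978% and 20.8 ± 0.865%. It was sly-miR159 in all libraries except infected replicates 1 and 2, where sly-miR482e-3p led. Sequences outside 20 to 24 nt, taken as a sign of degraded RNA, held 0.326 ± 0.0425% in healthy and 0.244 ± 0.0515% in infected libraries. Without 6 families listed after their values were seen as possible structural RNA, they held 0.0641 ± 0.00781% and 0.0503 ± 0.00721%. No sequence carried any of the animal microRNA prefixes searched, among those that the authors' pipeline had kept. The two-sided exact permutation p was 0.40 for the 21-nt and 22-nt shares, 0.70 for the 24-nt and top-sequence shares, 0.20 for the share outside 20 to 24 nt and 0.10 for predicted candidates. With 3 libraries against 3 the smallest p is 0.10, so no share could pass 0.05, and over the 6 shares the lowest Benjamini-Hochberg value was 0.60. The 21-nt and 22-nt differences of -1.84 and 1.87 percentage points were -0.373 and 0.366 without infected replicate 2, and -0.864 and 0.971 without healthy replicate 1. The 21-nt difference was -2.82 without healthy replicate 3. The difference in the 24-nt share changed sign without infected replicate 2 (to -0.00562 percentage points), and that in the top-sequence share without healthy replicate 3 (-0.214) or infected replicate 3 (-0.267).

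The second comparison was made sequence by sequence between infected and healthy apices. With 1 row used per sequence, the most abundant microRNAs were sly-miR159, sly-miR482e-3p, sly-miR482b, sly-miR166c-3p and sly-miR166a. Of these, sly-miR482e-3p, of a family that targets immune receptor genes, was at 173846 ± 13214 CPM (counts scaled to library size) in healthy and 199299 ± 15493 CPM in infected libraries. The values of sly-miR159, which targets MYB transcription factors, were 203488 ± 15572 and 173832 ± 41126 CPM, and those of sly-miR482b 142201 ± 6732 and 141589 ± 8829 CPM. The leaf polarity regulators sly-miR166c-3p and sly-miR166a had log2 fold changes of -0.00 (SE 0.15) and 0.08 (SE 0.14).

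No sequence passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 672 sequences. The lowest adjusted p was 0.0979, and 101 sequences had an unadjusted p under 0.05 (53 higher and 48 lower in infected libraries) where chance gives 33.6. This count of 101 was 63 without infected replicate 1. DESeq2 called 27 sequences, 13 higher and 14 lower. Among them were sequences of miR5368, miR6300, miR8175 and miR6173, families listed as possible structural RNA after their values were seen. With a pseudocount of 1, limma on the authors' normalized values called 0, with 183 at an unadjusted p under 0.05. It tested all sequences with a mean normalized value of at least 1, not the 672 of edgeR, so 183 cannot be set against 101 or 33.6. The edgeR test called 16 sequences without infected replicate 3 (5 higher, 11 lower) and 3 without healthy replicate 3 (2 higher, 1 lower). Sequences of miR6300, miR8175 and miR6173 were among those 16, and a miR6173 sequence was among those 3. The groups did not overlap in 177 sequences, 26.3% of those tested, where chance gives 10%.

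The 10 sequences with the smallest p are given with their values although none passed. The first belongs to the miR6173 family, listed after its values were seen as possible structural RNA resembling plastid ribosomal RNA. That origin was not checked. The smallest belonged to hbr-MIR6173-p3_1ss2CT (GTGCTGTAGCTAACGCGTTA), at 10.7 ± 3.21 CPM in healthy and 33.4 ± 0.814 CPM in infected libraries, a log2 fold change of 1.60 (SE 0.23). The next was the predicted 24-nt candidate PC-5p-28208_233 (TACACTGGGTTGGCGTAAGTTTGT), at 97.4 ± 16.5 and 19.8 ± 11.3 CPM (log2 fold change -2.27, SE 0.38). The candidate PC-3p-14950_398 was at 76.8 ± 19.7 and 28.0 ± 3.68 CPM. These 3 shared the adjusted p of 0.0979, and the other 7 shared 0.118, all in edgeR. PC-5p-207553_31 was listed at 0 in the 3 healthy libraries and at 23, 14 and 22 counts in infected replicates 1 to 3, and no fold is given against a group at 0. PC-5p-133140_53 was listed at 0, 0 and 6 counts in healthy and at 33, 43 and 43 in infected libraries. PC-3p-37609_180 was at 7.20 ± 1.16 and 21.9 ± 7.55 CPM.

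Among the named ones, sly-miR162 (TCGATAAACCTCTGCATCCAG), which targets a Dicer-like gene of the silencing machinery, was at 47651 ± 2654 CPM in healthy and 65921 ± 6751 CPM in infected libraries (log2 fold change 0.47, SE 0.11). The table places its hairpin on the plus strand of chromosome 6, from 43189935 to 43190030, in a genome build not given in the sources used here. The phosphate-responsive stu-miR399a-3p_1ss1TC was at 449 ± 255 and 112 ± 17.8 CPM (log2 fold change -2.0, SE 0.42). sly-miR171b-5p was at 92.8 ± 9.59 and 50.6 ± 7.29 CPM, and sly-MIR5300-p3 at 359 ± 47.2 and 216 ± 22 CPM. In all 10, the 3 infected values lay on one side of the 3 healthy values, which a choice by smallest p favours and so adds no support.

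The third comparison used sums over miRNA families, which do not depend on how reads were divided among length variants of a family. These sums too took 1 row per sequence. The miR399 family, induced by phosphate starvation, was at 698 ± 270 CPM in healthy and 245 ± 67.8 CPM in infected libraries, a log2 fold change of -1.51 (SE 0.33). The miR162 family was at 47794 ± 1362 and 67055 ± 10347 CPM (log2 fold change 0.49, SE 0.13). The miR160 family, which targets auxin response factors, was at 2558 ± 404 and 1843 ± 87.9 CPM (-0.47, SE 0.13). miR5304 was at 111 ± 17.5 and 52.3 ± 14.5 CPM (-1.08, SE 0.26). The groups did not overlap in these 4 families, each with the smallest p of a list, a choice that favours this. Of all 109 families tested, 28.4% did not overlap, where chance gives 10%.

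None of these family values passed the test. edgeR's quasi-likelihood test called 0 of 109 families, with a lowest adjusted p of 0.111 and 26 families at an unadjusted p under 0.05 (16 higher, 10 lower) where chance gives 5.45. Those 26 were 13 and 17 without infected replicates 1 and 2, and 15 and 17 without healthy replicates 1 and 2. DESeq2 called 12 families, 5 higher and 7 lower, among them miR399, miR162, miR160 and miR5304. Those 12 also held miR6173, miR5368 and miR6300, listed as possible structural RNA after their values were seen. Without infected replicate 3, edgeR called 5 families (1 higher, 4 lower), which were miR162 and miR5304, named by the rule, and miR858, miR6300 and miR8032, named after their values were seen. All 5 were also among the 12 of DESeq2.

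**Figure D2:**
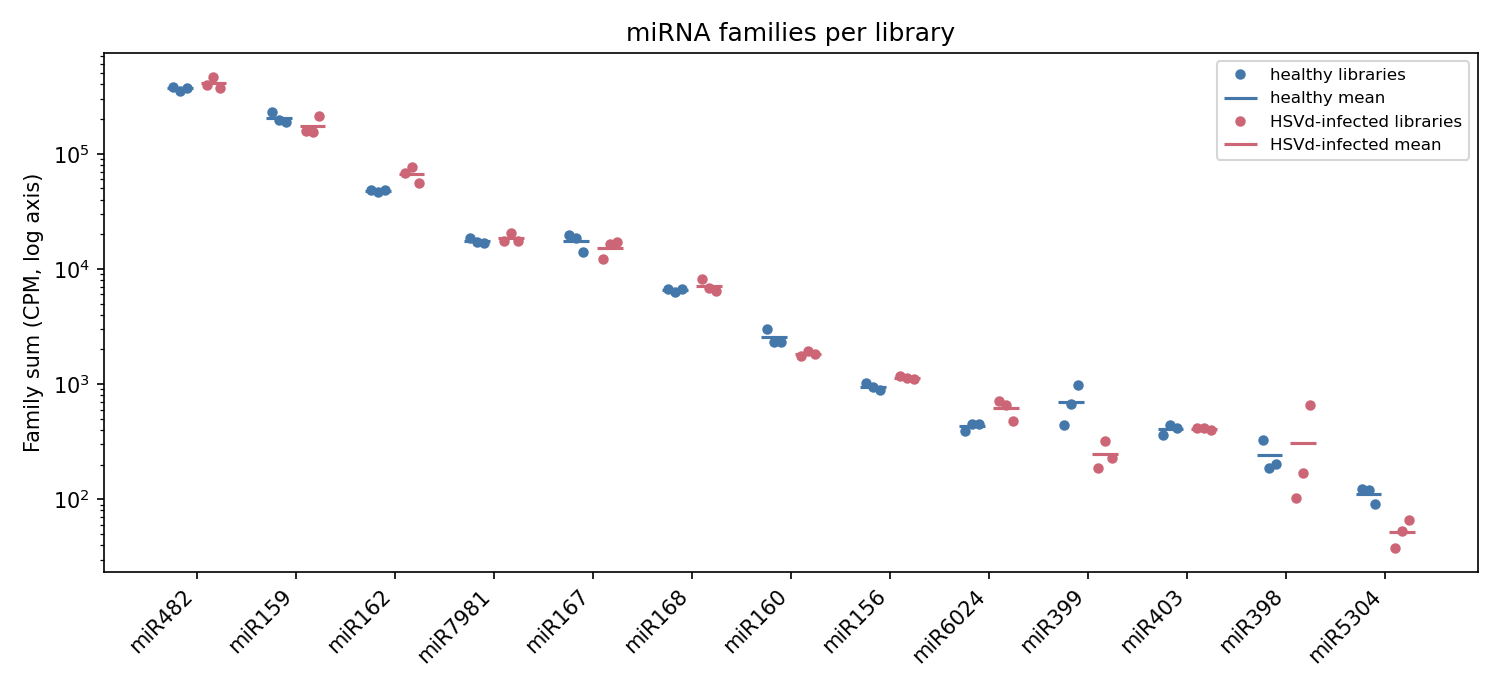
Summed level of 13 miRNA families in CPM on a log axis, with a point for each library and a line for each group mean, blue for healthy and red for HSVd-infected. The miR399 means are 698 and 245 CPM, and infected replicate 3 stands above the other libraries in miR398 at 652 CPM.

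**Figure D3:**
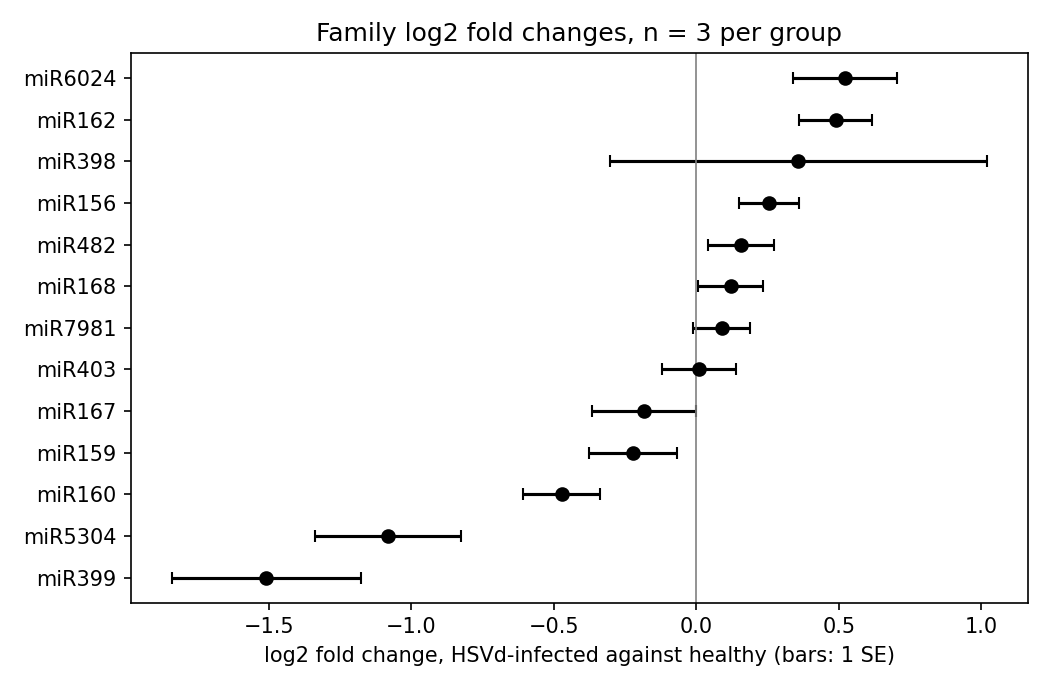
log2 fold changes of the same 13 families in HSVd-infected against healthy libraries, with bars of 1 SE (n = 3 per group). The values run from -1.51 for miR399 to 0.52 for miR6024, and none passed an adjusted p of 0.05 in edgeR.

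The lists fixed before the data were examined asked whether groups of microRNAs with a known role differed together. In the silencing list, the miR162, miR168 and miR403 families act on the plant's own silencing genes. The miR168 family was at 6563 ± 231 CPM in healthy and 7132 ± 881 CPM in infected libraries, and miR403 at 406 ± 39.7 and 409 ± 9.48 CPM. The miR403 log2 fold change of 0.01 (SE 0.13) was -0.06 with library totals. Of 11 tested silencing sequences, 10 had a positive log2 fold change. In edgeR 0 passed over all sequences tested, with 2 at an unadjusted p under 0.05, and adjusted over the list alone 1 passed, sly-miR162 (q = 0.0278), the one that DESeq2 also called. Of the 3 families, 1 passed adjusted over the list alone, miR162 (q = 0.0197).

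The immune receptor list takes every arm of families linked to immune receptor genes, so not each of its sequences need target one. Its miR482 family was at 370095 ± 14830 CPM in healthy and 412153 ± 49454 CPM in infected libraries. miR6024 was at 432 ± 37.8 and 619 ± 126 CPM (log2 fold change 0.52, SE 0.18). Of the 26 tested sequences 13 had a positive and 13 a negative log2 fold change. None passed over all sequences or adjusted over the list alone (lowest q = 0.0519), with 5 at an unadjusted p under 0.05 in edgeR. DESeq2 called 3 of them, sly-MIR5300-p3 and 2 chosen after their values were seen, sly-miR482d-3p and sly-miR482e-5p.

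In the nutrient list, miR399 lay lower and miR395, which answers to sulfate supply, lay higher in infected libraries (miR395 at 4.99 ± 1.41 and 14.6 ± 6.16 CPM). Of 20 tested sequences 11 had a positive log2 fold change in edgeR, as had 5 of 7 families. In edgeR 0 passed over all sequences, with 4 at an unadjusted p under 0.05 and 2 called by DESeq2. Adjusted over the list alone 4 passed: stu-miR399a-3p_1ss1TC, sly-miR399 and gma-miR399i with log2 fold changes of -2.0, -1.40 and -1.84, and sly-miR395a_R-1 with 1.51. Of the families, 2 passed adjusted over the list alone, miR399 (q = 0.0190) and miR395 (q = 0.0280). Apart from stu-miR399a-3p_1ss1TC and the miR399 family, these were named after their values were seen. The miR395 family holds 1 sequence, sly-miR395a_R-1, so both results rest on the same low counts. Those were 9, 3.5 and 13 in healthy and 21, 23.5 and 59.5 in infected replicates 1 to 3. The miR395 log2 fold change ran from 1.09 to 1.74 with each library left out. The copper-responsive miR398 family was at 240 ± 77.4 and 308 ± 300 CPM. Its log2 fold change of 0.36 (SE 0.66) was -0.83 without infected replicate 3.

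In the development list of 87 tested sequences, 52 had a positive log2 fold change and none passed over all sequences or adjusted over the list alone (lowest q = 0.110). The miR159 family was at 204724 ± 21971 CPM in healthy and 175472 ± 32521 CPM in infected libraries. In the auxin list, all 4 families had a negative log2 fold change, while 11 of 26 sequences had a positive one. miR167 was at -0.18 (SE 0.18), and at -0.0777 without infected replicate 1, -0.115 without healthy replicate 1 and -0.303 without healthy replicate 3. In edgeR miR160 passed adjusted over the auxin list alone (q = 0.0395), with 0 of the 26 sequences passing either way. It did not pass adjusted over the development list, which also holds it (q = 0.115). Values adjusted over a list alone were not adjusted across the lists. In the phase list, miR156, which delays the adult phase, was at 953 ± 63.4 and 1137 ± 44.2 CPM, and 11 of 13 sequences had a positive log2 fold change, with 0 passing either way. In the list of other families known from Solanaceae, 34 of 71 sequences had a positive log2 fold change and 0 passed either way, with miR7981 at 17449 ± 916 and 18556 ± 1723 CPM. In these 4 lists, 11, 3, 2 and 10 sequences had an unadjusted p under 0.05 in edgeR, and DESeq2 called 3, 1, 1 and 2.

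As whole sets, 0 of 11 passed limma's camera test at an adjusted p of 0.05 with a preset correlation of 0.01. An unadjusted p under 0.05 was found for silencing (0.0263, higher), nutrient (0.0380, lower) and 24-nt sequences (0.0405, higher), each with an adjusted p of 0.148. The nutrient set had a median of -0.19 and a mean of -0.37 on camera's log2 CPM scale, although 11 of its 20 sequences had a positive log2 fold change in edgeR. With an estimated correlation the adjusted p was 0.530 for these 3 sets. Of 367 tested 24-nt sequences, 213 had a positive log2 fold change, against 90 of 173 with 21 nt, 29 of 60 with 22 nt, and 126 of 294 predicted candidates had a negative one. In these 4 sets 0 sequences passed in edgeR over all sequences or adjusted over the list alone, with 34, 36, 12 and 33 at an unadjusted p under 0.05 and 5, 10, 5 and 6 called by DESeq2. fry's test of change in either direction gave an adjusted p under 0.05 for all sets except auxin, phase and nutrient (lowest 0.00293, for predicted candidates), and its test of 1 direction gave none (lowest 0.232). The immune receptor set had a median of 0.00 and a mean of -0.06, the Solanaceae set a median of -0.02 and a mean of 0.04, and the 21-nt set a positive median and mean with a camera direction below the other sequences. The development set had a mean of 0.09 and differed from the other sequences by -0.02 while camera placed it above them. With all 6 libraries but no filter, camera called 3 sets (nutrient, 21 nt and 24 nt). It called 3 sets without infected replicate 3 (silencing, nutrient and 24 nt), 1 without healthy replicate 2 (24 nt) and 1 without infected replicate 2 (nutrient). The mean log2 fold change of the nutrient set minus that of the other sequences, -0.481, was -0.0741 without infected replicate 1 (unadjusted p = 0.894 in limma's camera test) and -0.794 without infected replicate 3. That of the silencing set, 0.113, was 0.0423, 0.0516 and 0.197 without infected replicates 1, 2 and 3, and -0.00470 and 0.0743 without healthy replicates 1 and 3.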

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

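All the alternatives were planned except the counts summed over rows, the filter for values above 0 in all 6 libraries, the robust fit, those of the share outside 20 to 24 nt and those of microRNAs named after their values were seen, which were chosen after seeing the data. The count of called sequences, 0 in edgeR, was 27 with DESeq2, 5 with limma at a pseudocount of 10, 2 with sequences above 0 in all 6 libraries, and 0 to 16 with each library left out. The count of called families, 0, was 12 with DESeq2 and 0 to 5 with each library left out. Of the DESeq2 calls tested in edgeR, all 26 sequences and 12 families had the same sign and an unadjusted p under 0.05 there, and 8 sequences and 5 families were also called without infected replicate 3. The count of called lists, 0, was 3 without a filter (nutrient, 21 nt, 24 nt) and 0 to 3 with each library left out. The cause of these shifts was not tested. All other settings gave 0.

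The correlations of same-numbered libraries' deviations were -0.0948, 0.0801 and -0.130. They give no sign that the numbers pair the samples, but so few libraries per group cannot exclude it. With the replicate number as a block, 0 sequences, 0 families and 0 lists were called, with 75 sequences and 17 families at an unadjusted p under 0.05.

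Of the 46 named sequences and families, 18 of them named after their values were seen, 756 of 829 alternative values kept their direction and side of the threshold, 41 passed it in the same direction and 32 changed sign. For sly-miR166c-3p (main log2 fold change -0.000277) the value was 0.00652 with RLE, 0.0218 with every row, 0.00175 with DESeq2, 0.00245 with limma at pseudocounts 1, 0.1 and 10, 0.0114 above 0 in all 6 libraries and -0.0919 to 0.142 with each library left out. For sly-miR482b (-0.00623) it was 0.0138 with every row, 0.00129 with limma at the 3 pseudocounts, 0.00717 above 0 in all 6 libraries and -0.0388 to 0.0477 with each library left out. For miR403 (0.00790) it was -0.0592 with library totals, -0.00470 with counts summed over rows and -0.0930 to 0.0679 with each library left out. miR398 (0.357) was -0.0587 with the block and -0.828 to 0.732 with each library left out, miR168 (0.120) -0.0298 to 0.197 and sly-miR166a (0.0825) -0.0621 to 0.210. Among those named later, miR827 (0.203) was -0.215 with the block and -1.02 to 0.588 with each library left out, miR2916 (0.0770) -0.0456 to 0.134, miR408 (0.424) -0.525 to 0.772 and miR397 (0.858) -0.100 to 1.21.

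For lists, the mean log2 fold change minus that of other sequences changed sign for silencing (0.113), to -0.0246 without a filter and -0.00470 to 0.197 with each library left out. The phase list (0.207) was -0.0274 without a filter and -0.0225 to 0.338 with each library left out. The development list (-0.0159) was 0.0808 at a mean of at least 10 CPM, 0.113 with named sequences only and -0.0897 to 0.0256 with each library left out. The auxin list (-0.132) was 0.0269 and other Solanaceae families (-0.0614) were 0.0635 at a mean of at least 10 CPM, and the latter 0.0561 with named sequences only. Among shares, the 24-nt difference (0.0752 points) ran from -0.00562 to 0.150 and the top-sequence difference (0.219 points) from -0.267 to 0.749 with each library left out. The cause was not tested. In simulations at this depth and the trended spread, with 200 sequences changed in each, 42.4% of 2-fold changes in sequences were recovered. The share may be lower in the real data.

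Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 0 called sequences, families and lists (highest other 0, 0 and 3), so all 10 gave as many by construction, which says nothing about chance. At an unadjusted p under 0.05 the real split gave 101 sequences (highest other 46) and 26 families (highest other 13), the highest in 1 of 10 splits each. Without infected replicate 1 the real counts were 63 and 13, and the families 15 and 17 without healthy replicates 1 and 2 and 17 without infected replicate 2. With 10 splits no share under 0.05 can be had. These split tests were written down after their counts were seen.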

Other observations

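The tests of miR399 and of the families listed as possible structural RNA, the list itself, and the correlations, were chosen only after the results were seen; the thinning tests were written down before they were run. The copper-responsive families were set apart by 1 library; miR398 was named by the rule, and miR408 and miR397 after their values were seen. In infected replicate 3, miR398 was at 652 CPM, miR408 at 946 CPM and miR397 at 188 CPM, against 102 and 169, 183 and 318, and 35.2 and 63.6 CPM in infected replicates 1 and 2. Correlations were computed on log2(CPM + 1). Across the 6 libraries miR398 went with miR408 (Pearson r = 0.990, exact permutation p = 0.00417, adjusted 0.0125, and Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.050). Without infected replicates 1 and 3, the 2 libraries farthest from the median of miR398 on that log scale, r was 0.925. For miR398 with miR397, r was 0.918 (exact permutation p = 0.0125, adjusted 0.0188) and rho 0.771 (exact permutation p = 0.103, adjusted 0.136), and r without those libraries was 0.539, so this relation rests on them. For miR6300 with miR8175, r was 0.773 (exact permutation p = 0.0736, adjusted 0.0736) and rho 0.714 (exact permutation p = 0.136, adjusted 0.136), with -0.163 without infected replicates 1 and 2. These 3 relations were all that were computed.

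More low-count sequences stood above 0 in infected libraries, by 208 on average. After thinning to the smallest library with a minimum of 5 reads the difference was 24.2 (SD 5.90 over 20 draws), so depth with a read minimum may account for most of it. The lean of 24-nt sequences, a mean log2 fold change 0.247 above that of the others on counts summed over rows, was 0.240 (SD 0.0273) after the same thinning, which argues against depth as its cause. With all 6 libraries the lean did not pass the camera test under the default filter (0.273) but did without a filter (0.309, adjusted p = 0.0221, with 0.0221 to 0.530 over the alternatives), and it passed without infected replicate 3 (0.379) or healthy replicate 2 (0.332). It was 0.221 without infected replicate 2 (camera's adjusted p in limma 0.366) and 0.178 at a mean of at least 10 CPM (0.383), and viroid infection stays open and untested as an explanation.

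The miR399 family lay lower in infected libraries without passing edgeR's test, though DESeq2 called it. Its log2 fold change minus the median over all tested families was -1.59 (SE 0.33, that of the family alone). TMM scaling brings this median near 0 (0.0769), so the outcome was close to fixed and does not decide about scaling between libraries. The miR399 log2 fold change was -1.52 with RLE and -1.60 with library totals, so it moved little with the scaling used. A weaker phosphate starvation response may be a candidate explanation, but 2 other phosphate-responsive families do not decide it, with miR827 at 0.20 (SE 0.68) and miR2111 at -0.59 (SE 0.27). The sign of miR827 rests on infected replicate 2, at 682 CPM against 104 and 169 CPM in the other infected libraries: without it the log2 fold change was -1.02 (SE 0.35, unadjusted p = 0.0279, adjusted 0.276 in edgeR, with 0.276 to 0.981 over the alternatives), the direction this explanation needs, and it was -0.0187 without healthy replicate 3 and -0.215 with the replicate block. Whether infection or growth conditions set these levels cannot be told apart here, because phosphate supply was not recorded in the labels.

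The 6 families with miRBase names that were listed as possible structural RNA, from general knowledge, lay on both sides of 0, none past edgeR's threshold with all 6 libraries, while DESeq2 called miR6173 (adjusted p = 0.000423), miR5368 and miR6300 (0.0330 each; highest over the alternatives 0.276, 0.352 and 0.418), and edgeR called miR6300 at a log2 fold change of -2.84 without infected replicate 3. The list classed miR6300, miR8175 and miR6478 as like transfer RNA. It classed miR6173 and miR5368 as like plastid and miR2916 as like nuclear ribosomal RNA. miR6300 was at 421 ± 174 CPM in healthy and 119 ± 109 CPM in infected libraries, and miR8175 at 2542 ± 508 and 1762 ± 385 CPM. miR6173 was at 41.1 ± 14.5 and 111 ± 4.69 CPM and miR5368 at 2594 ± 372 and 3565 ± 157 CPM (SD, n = 3). A listed hairpin on chromosome 3 (69945093 to 69945165, build not given in the sources used here) holds a 72-nt stretch with the features of a transfer RNA. The stretch was chosen to hold the reference entry of miR6300 and that of miR8175 without its CCA end. Of their other 23 sequences, 100% lie in it with 1 mismatch and an added CCA end allowed. These carry names built on the same 2 references, so that outcome was close to fixed. The shared hairpin leaves a common origin possible, in transfer RNA that the authors' filter left. The other 2 families were miR6478 (log2 fold change -0.18, SE 0.18; -0.348 and -0.0676 without infected replicates 1 and 3, -0.273 and -0.0978 without healthy replicates 1 and 2) and miR2916 (0.08, SE 0.11; -0.0456 without infected replicate 1), and the origin of the 4 families other than miR6300 and miR8175 stays unchecked, except that 0 sequences of miR6478 and miR6173 lie in that stretch. Degraded RNA and infection both stay open: the share of counts outside 20 to 24 nt was -0.0823 percentage points in infected minus healthy libraries (exact permutation p = 0.20), the same sign as miR6300 and miR8175, but the 6 families hold 77.3% to 84.8% of that share, and without them the difference was -0.0138 points (exact permutation p = 0.20).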
